A study of Lotus japonicus with 18 samples.

How the data were processed

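RNA was measured by sequencing in shoots of Lotus japonicus, a model legume, after 30 days of growth. Wild type (WT) and mutant lines 1 and 2 (Ljmyb36) were kept in visible light alone (control) or given UV-B with the visible light for 16 h, and tissue was harvested 4 h into the light period. Each of the 6 groups holds 3 libraries, 18 in all. Per the labels, RNA was extracted with CTAB, polyadenylated RNA was bound to poly-T beads, and libraries were made with random hexamers and dUTP in the second strand. The submitters' processing notes name fastp for trimming, featureCounts 1.5.0-p3 for counting and, for the submitters' own tests, DESeq2 1.20.0; the genome build is not given in the sources used here, and neither is the strand setting of the counting. Coordinates are printed as deposited. The labels call the replicates biological replicates, but nothing says whether they came from separate plants or pots, so p-values measure the spread between these samples.

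The deposited table gives FPKM values made by the authors for 33994 gene models, 30584 of them LotjaGi models and 3410 additional models assembled by the authors; 22023 carry a Swiss-Prot hit and 2259 a transcription factor family, while 130 lie on the plastid genome and 73 on the mitochondrial genome. Every per-sample column of the table was used. Each FPKM value multiplied by the gene length was a whole multiple of 1 step per library (100% of values, tolerance 0.1 read), which gave back whole read counts: 50706923 to 81576950 reads per library. The library size in the authors' FPKM is not the read total: reads divided by that size ran from 0.832 to 0.984 in control libraries and from 1.04 to 1.18 in UV-B libraries, and the implied scaling matched median-of-ratios factors to within ratios of 0.985 to 1.01. At 1 kb, 1 read equals 0.0107 to 0.0228 FPKM. The number of reads per independent molecule, estimated from how often genes of 0.05 to 0.5 FPKM were listed at 0, ran from 2.7 to 51.6, and 6 libraries lay above 20: WT control 1 (21.2), WT UV-B 3 (36.0), line 1 control 1 (51.6), line 1 control 2 (38.5), line 1 UV-B 2 (21.9) and line 1 UV-B 3 (27.6). Plastid genome transcripts took 0.651% of reads in WT control 1 and 0.102 to 0.349% in the others. Correlations of log2 values within groups were 0.949 to 0.994.

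Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with trend and robust). Genes with at least 1 FPKM in at least 3 libraries were tested, 21064 in all. A model of 6 group means over the 18 libraries (12 residual and 5.17 prior degrees of freedom) gave 9 contrasts: UV-B against control in each of the 3 genotypes, each line against WT in control light and under UV-B, and each line's UV-B response minus that of WT. A gene passed at a Benjamini-Hochberg adjusted p below 0.05 within a contrast. A gene differed in both lines when it passed in both with the same sign. Fold changes on this scale understate changes of genes near 0 FPKM. Positive values mean higher under UV-B, or higher in the mutant. The WT libraries enter both lines' comparisons, so overlap was simulated with 20 data sets without differences. The noise there was drawn independently for each gene and library, so shifts of whole libraries are not simulated. On data with 200 simulated changes per comparison, the test found 23.9% of changes of 1.5-fold, 76.1% of 2-fold and 98.5% of 4-fold for line 1 against WT in control light, with 8 false calls, and 20.9, 80.6 and 100% under UV-B, with 7 false calls. The changed genes had a WT mean of at least 5 FPKM, and noise was independent between genes. Lower genes and shifts of whole libraries are thus not covered.

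The 24 gene lists were: phenylpropanoid core, early flavonoid, isoflavonoid, anthocyanin and proanthocyanidin, lignin, UV-B signalling, DNA repair, nuclear photosynthesis genes, chlorophyll loss and senescence, redox and detoxification, defence (pathogenesis-related), heat shock, jasmonate, ERF and WRKY factors, auxin response, cell cycle and histones, clock, Casparian strip and suberin, cytosolic ribosome, root and nodule markers, reproductive markers, epidermis and wax markers, phloem and xylem markers, and plastid-encoded genes. The last 5 stand for other organs, tissues and RNA quality. Lists were drawn from words of the deposited annotation, with at least 5 tested members each. They were tested with camera in limma at an inter-gene correlation of 0.01, 216 tests adjusted over lists within a contrast, and again with the correlation estimated from the data. Of 70 calls, 2 hold with the estimated correlation: epidermis and wax markers under UV-B in WT, and the jasmonate list in the response difference of line 1. Counts of members past the threshold are given over all genes and adjusted over the list alone.

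Genes were named by a rule. It took every tested gene annotated as MYB36, and the 5 rising and 5 falling genes of largest log2 change past the threshold. The latter needed replicate ranges that do not overlap, a mean of at least 5 FPKM in the higher group and an annotated function. Up to 4 such members of each list were added, or the 1 or 2 members of highest mean where none passed. For both lines the smaller of the 2 changes ranked the genes. The groups, contrasts, tests, gene lists, this rule and the alternatives named next were chosen before the data were examined: a pseudocount of 0.1, no filter, a filter at 5 FPKM, quantile normalization, only the groups of a contrast in the fit, the replicate number as a block, a 2-fold threshold, an estimated correlation for the lists, and each library left out in turn. Array weights, the number of reads per molecule as a covariate, a fit without the 6 libraries above 20 reads per molecule, voom on the recovered reads, and the lists with each library left out were added after the data were seen. Groups were also split in all other ways (up to 100 splits). Correlations of same-number libraries of different groups, after group means were removed, ran from -0.179 to 0.293. All 3 were above 0.1 between WT control and line 2 control, line 1 control and line 2 UV-B, and line 1 UV-B and line 2 UV-B, so pairing by number is not excluded. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Raw reads were not analysed here.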

Results

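The data are 18 shoot libraries of Lotus japonicus, a legume that makes isoflavonoids. WT and 2 Ljmyb36 mutant lines were kept in control light or given UV-B for 16 h. Each of the 6 groups has 3 libraries, with 50706923 to 81576950 reads per library. The question behind the series is whether loss of the transcription factor MYB36, known in Arabidopsis for its role in forming the Casparian strip of the root endodermis, alters flavonoid and isoflavonoid gene expression. UV-B separated the libraries most: the 1st principal component held 83% of the variance, from -103 to -65.2 in control libraries and from 82.6 to 94.8 in UV-B libraries, and the 2nd held 3.1%. Values are mean FPKM with SD over 3 libraries, and changes are log2 with SE and adjusted p from limma.

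Of the genes tested, the annotation names 5 as MYB36. Models below the FPKM filter were not searched for that name, and the labels do not say which gene is disrupted. Of these 5, LotjaGi4g1v0298100 (chromosome 4, 67211036 to 67213329) was the 1 whose level differed between genotypes. Under UV-B it stood at 8.87, 10.4 and 12.7 FPKM in WT, 4.68, 5.43 and 3.85 in line 1 and 3.40, 2.74 and 3.51 in line 2. The difference was -1.04 in line 1 (SE 0.21, adjusted p 0.0195) and -1.46 in line 2 (adjusted p 0.00203). In control light it was near the floor, with 1.38, 0.2 and 0.371 FPKM in WT, 0.15, 0.384 and 0.394 in line 1 and 0.252, 0.229 and 0.19 in line 2. There the differences were -0.27 and -0.37 (adjusted p 0.629 and 0.46). UV-B raised it in WT, from 0.651 (SD 0.64) to 10.7 (SD 1.9), a change of 2.88 (SE 0.21, adjusted p 2.89e-09). It rose in the lines by 2.10 and 1.78. These responses differ from that of WT by -0.77 and -1.10 (adjusted p 0.438 and 0.185), and the test for a weaker response is passed in line 2 only without WT control 1 (-1.39, adjusted p 0.0462, and 0.16 in line 1). The call in line 1 under UV-B is lost without WT UV-B 2 (adjusted p 0.0622), WT UV-B 3 (0.0556), line 1 UV-B 1 (0.0575), line 1 UV-B 2 (0.0522) or line 1 UV-B 3 (0.0782). It is also lost with only the groups compared (0.0819). With a pseudocount of 0.1 both lines' calls are lost (0.259 and 0.0921).

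The other 4 did not differ between genotypes in control light (adjusted p 0.359 to 0.93) or under UV-B (0.568 to 0.998). LotjaGi4g1v0091600 had 9.04, 6.05 and 5.87 FPKM in WT control, 6.12, 5.58 and 7.02 in line 1 and 7.04, 6.7 and 7.98 in line 2. Under UV-B it had 3.37, 3.01 and 1.73, then 2.9, 2.25 and 2.34, then 3.92, 3.05 and 2.57. It fell in WT by 1.11 (SE 0.19, adjusted p 5.89e-05). LotjaGi3g1v0486500 rose in WT by 1.64 (adjusted p 1.3e-06). It had 1.11, 0.782 and 0.272 in WT control, 0, 0.509 and 0.262 in line 1 and 0.831, 0.355 and 0.453 in line 2. Under UV-B it had 5.1, 4.16 and 3.63, then 6.01, 5.49 and 4.78, then 4.67, 3.82 and 3.85. LotjaGi1g1v0688400 had 2.28, 2.43 and 1.65 in WT control, 1.66, 1.03 and 1.46 in line 1 and 1.36, 1.4 and 1.85 in line 2. Its UV-B values were 1.43, 1.37 and 0.75, then 1.33, 0.841 and 0.776, then 1.27, 1.18 and 0.533. Its fall in WT (-0.52, adjusted p 0.0263) is lost without WT control 1 (0.0705), WT control 2 (0.0928) or WT UV-B 3 (0.125) and with quantile normalization (0.131). LotjaGi3g1v0167900 had 0.869, 0.307 and 0.19 in WT control, 0.172, 0.696 and 0.0892 in line 1 and 0.232, 0.0765 and 0.245 in line 2. Its UV-B values were 1.07, 0.728 and 1.26, then 1.22, 1.47 and 1.96, then 0.786, 1.44 and 0.864. Its change was 0.49 in WT (adjusted p 0.0526).

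**Figure D1:**
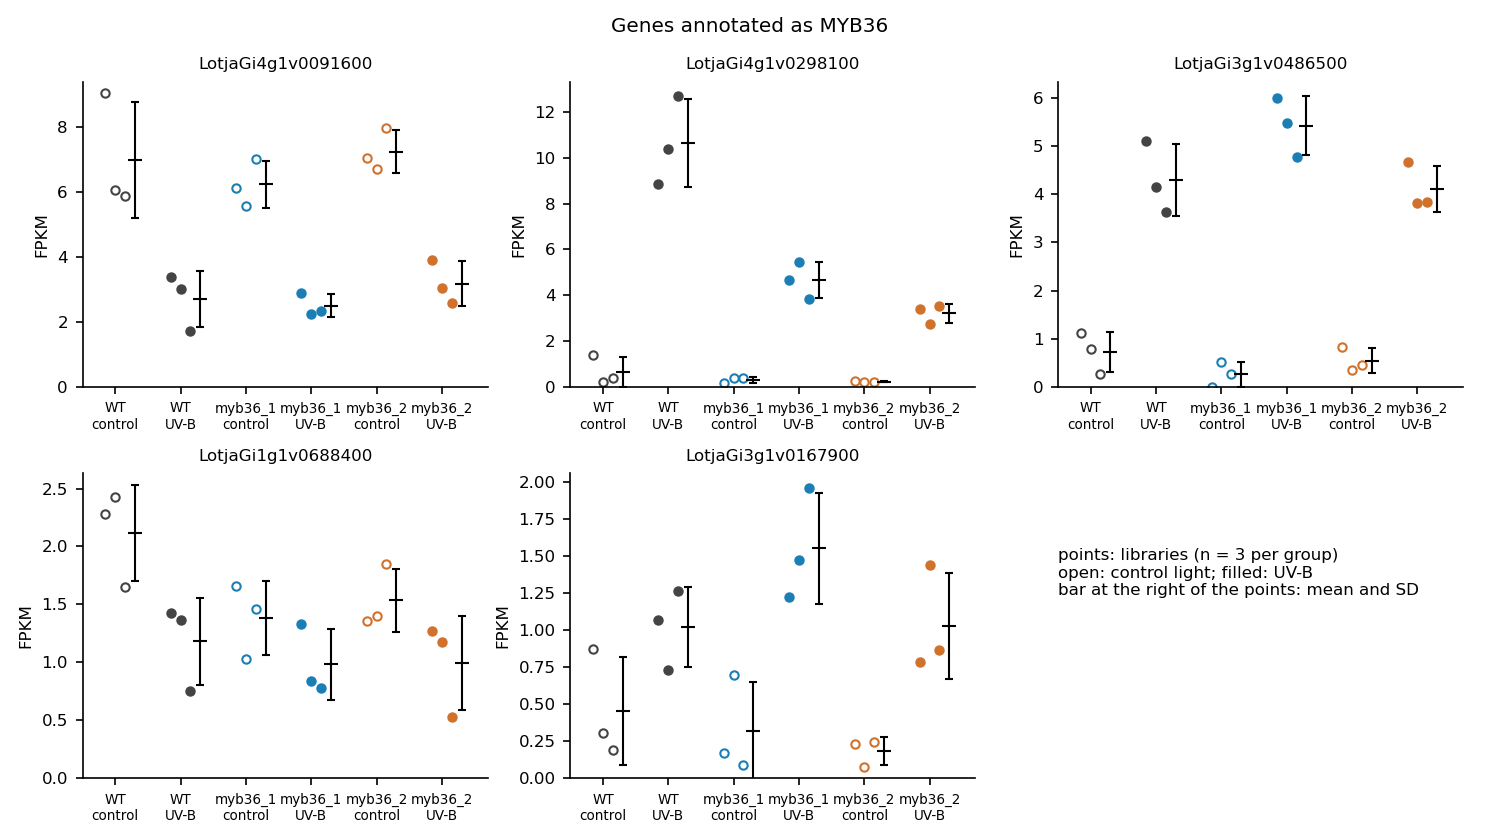
FPKM of the 5 tested genes annotated as MYB36 in each of the 18 libraries, by group (points are libraries, open in control light and filled under UV-B, bars are mean and SD, n = 3). LotjaGi4g1v0298100 has a mean of 10.7 FPKM in WT under UV-B, against 4.65 in line 1 and 3.21 in line 2.

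In WT, 16 h of UV-B raised the lists of phenylpropanoid, early flavonoid and isoflavonoid genes and lowered those of nuclear photosynthesis genes and of epidermis and wax markers. With an estimated correlation the wax list alone keeps its call (adjusted p = 0.0387), and the other 4 have adjusted p = 0.34 to 0.394. Of 21064 genes tested, 6566 rose and 6206 fell, and in 12093 of these 12772 the replicate ranges do not overlap (10% of genes would stand apart by chance with 3 against 3). The largest rise was that of a glutathione S-transferase, LotjaGi5g1v0258400, from 14.9 (SD 10.8) to 1420 FPKM (SD 229, log2 6.85, SE 0.61, adjusted p 1.06e-07). Another such gene, annotated parA, followed (LotjaGi6g1v0043900, 5.13 to 368, log2 6.09). An aminocyclopropane carboxylate synthase, which makes the precursor of ethylene, rose from 0.445 to 95.1 (LotjaGi1g1v0481200, log2 6.05, SE 0.32, adjusted p 1.02e-10). Next came a mannitol dehydrogenase, LotjaGi2g1v0329400 (0.459 to 69.4, log2 5.67), and a class-10 pathogenesis-related protein, LotjaGi3g1v0114700 (36.4 to 1609, log2 5.51). The largest falls were the auxin-binding protein ABP19a, LotjaGi3g1v0415000 (553 to 8.01, log2 -6.11), and a 9S-lipoxygenase-3, LotjaGi3g1v0420500 (385, SD 139, to 6.14, SD 2.22, log2 -5.74, SE 0.26, adjusted p 1.44e-11). They were followed by gibberellin-regulated protein 6, LotjaGi1g1v0219700 (182 to 3.03, log2 -5.49), thiamine thiazole synthase 2, LotjaGi5g1v0317600 (1336 to 29.7, log2 -5.46), and proline-rich protein 4, LotjaGi3g1v0531300_LC (181 to 3.72, log2 -5.25).

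The pathway from phenylalanine to isoflavonoids rose together. In the phenylpropanoid core list 15 of 19 tested members rose and 1 fell, over all genes and adjusted over the list alone (median 1.58, adjusted p 6.64e-05, and adjusted p = 0.34 with an estimated correlation). Phenylalanine ammonia-lyase, the entry enzyme, LotjaGi6g1v0093700, went from 7.23 (SD 3.76) to 270 FPKM (SD 38.3, log2 5.15, SE 0.44). Cinnamate 4-monooxygenase LotjaGi6g1v0044200 rose from 13.2 to 143 (log2 3.32) and 4-coumarate--CoA ligase 2, LotjaGi2g1v0450000, from 35.3 to 250 (log2 2.85). In the early flavonoid list 27 of 41 rose and 7 fell, likewise adjusted over the list alone (median 1.79, adjusted p 0.00185, and adjusted p = 0.394 with an estimated correlation). Chalcone synthase, which builds the flavonoid skeleton, rose as LotjaGi3g1v0078700 (72.1, SD 39, to 890, SD 109, log2 3.80) and LotjaGi2g1v0450100 (22.4 to 344, log2 4.08). The 6'-deoxychalcone synthase LotjaGi4g1v0144700, which diverts chalcones to the deoxy isoflavonoids of legumes, rose from 16.8 to 284 (log2 4.36). In the isoflavonoid list 19 of 23 rose and 1 fell, also adjusted over the list alone (median 2.79, adjusted p 6.08e-06, and adjusted p = 0.34 with an estimated correlation). At the step into isoflavones, 2-hydroxyisoflavanone synthase LotjaGi4g1v0063900 rose from 64.2 (SD 44.5) to 867 (SD 6.45, log2 4.13). Its partner 2-hydroxyisoflavanone dehydratase, LotjaGi1g1v0018600, rose from 10.1 to 352 (log2 5.03) and pterocarpan synthase LotjaGi1g1v0277900 from 68 to 1361 (log2 4.45).

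In the list of the branch to anthocyanins and proanthocyanidins more members fell than rose: of 17 members 3 rose and 10 fell, also adjusted over the list alone. The median of -1.01 missed the threshold (adjusted p 0.0605). Anthocyanidin glucosyltransferase LotjaGi4g1v0047500 fell from 46.9 to 7.87 (log2 -2.39), leucoanthocyanidin dioxygenase LotjaGi2g1v0429400 from 18.4 to 3.55 (log2 -2.18) and anthocyanidin reductase LotjaGi4g1v0045700 from 16.9 to 3.26 (log2 -2.07). Dihydroflavonol 4-reductase LotjaGi5g1v0013700 rose from 27.2 to 328 (log2 3.58). In the lignin list 18 of 44 rose and 9 fell (adjusted over the list alone 18 and 9, adjusted p 0.153). Caffeic acid 3-O-methyltransferase LotjaGi1g1v0005500 rose from 22.3 to 247 (log2 3.46) and laccase-7, LotjaGi1g1v0218900, from 7.86 to 70.2 (log2 3.22).

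Photosynthesis genes fell almost throughout: 55 of 61 nuclear members fell and 3 rose (adjusted over the list alone 55 and 4, median -2.23, adjusted p 9.36e-19, and adjusted p = 0.34 with an estimated correlation). Chlorophyll a-b binding protein 40, LotjaGi2g1v0128900, went from 119 (SD 23) to 2.62 FPKM (SD 1.3, log2 -5.09). Protein 3C, LotjaGi2g1v0129100, fell from 738 to 39.3 (log2 -4.19) and the Rubisco small subunit LotjaGi1g1v0550100 from 2838 (SD 432) to 182 (SD 52.5, log2 -3.98). STAY-GREEN genes, which act in chlorophyll breakdown, rose (LotjaGi4g1v0217600, 7.76 to 64.5, log2 2.99, and LotjaGi2g1v0429900, 4.61 to 25.3, log2 2.23). In the chlorophyll loss list 15 of 27 rose and 7 fell (adjusted over the list alone 16 and 7, adjusted p 0.153). Epidermis and wax markers fell in 21 of 27 and rose in 5, also adjusted over the list alone (median -1.30, adjusted p 5.01e-05, and adjusted p = 0.0387 with an estimated correlation). ECERIFERUM 26, which acts in elongation of wax precursors, LotjaGi4g1v0371900, fell from 120 (SD 14) to 2.52 (SD 0.63, log2 -5.10, SE 0.19). A fatty acyl-CoA reductase, LotjaGi3g1v0175300, fell from 79.5 to 5.03 (log2 -3.73), and 3-ketoacyl-CoA synthase 6, LotjaGi5g1v0340300, from 114 to 15.1 (log2 -2.82).

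The UV-B signalling list as a whole missed the threshold, with 14 of 30 rising and 9 falling (adjusted over the list alone 14 and 9, adjusted p 0.198). Its members that rose include a gene annotated as the photoreceptor UVR8 (LotjaGi6g1v0067100, 0.644 to 7.22, log2 2.33, SE 0.17), B-box proteins 18 (LotjaGi2g1v0383700, 2.33 to 19.8, log2 2.65) and 24 (LotjaGi3g1v0032800, 4.63 to 32.5, log2 2.59). So did an early light-induced protein, known from photoprotection (LotjaGi5g1v0310100, 41.9 to 348, log2 3.04). In DNA repair 14 of 69 rose and 18 fell (adjusted over the list alone 13 and 17, adjusted p 0.847). The repair factor TFB1 LotjaGi5g1v0258200 (3.85 to 68.6, log2 3.84) and REV1 of translesion synthesis, LotjaGi2g1v0461300 (2.46 to 19.8, log2 2.58), rose. DRT100 LotjaGi1g1v0010700 fell (7.63 to 0.197, log2 -2.85). The list's median is 0.03, its mean -0.01 and its test points down. ERF and WRKY factors rose in 75 of 147 and fell in 34 (adjusted over the list alone 75 and 36, adjusted p 0.0078, and adjusted p = 0.449 with an estimated correlation). ERF110, LotjaGi2g1v0128200, went from 2.39 to 102. In redox and detoxification 38 of 86 rose and 28 fell (39 and 31 adjusted over the list alone, adjusted p 0.178). In the heat shock list 38 of 96 rose and 15 fell, also adjusted over the list alone (adjusted p 0.113). The heat shock factor HSF24, LotjaGi4g1v0055500, rose from 0.807 to 46.8 (log2 4.73). In defence 45 of 119 rose and 41 fell (45 and 43 adjusted over the list alone, adjusted p 0.977, median -0.04, mean 0.34, test down). Thaumatin-like protein 1, LotjaGi1g1v0685000, rose from 3.18 to 147 (log2 5.23).

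The jasmonate list had 22 of 58 members rising and 17 falling, also adjusted over the list alone (adjusted p 0.745). The rises included 12-oxophytodienoate reductase 3, LotjaGi4g1v0325700, an enzyme of jasmonate synthesis (9.53, SD 1.4, to 183, SD 21, log2 4.13, SE 0.16). The 9S-lipoxygenase LotjaGi3g1v0420500, the list member that fell most, makes 9-hydroperoxides, which are not precursors of jasmonate. Auxin response genes fell in 36 of 81 and rose in 19, also adjusted over the list alone (adjusted p 0.144, auxin-induced protein 15A, LotjaGi3g1v0517600, 9.72 to 0.22, log2 -3.13). Cell cycle and histone genes fell in 29 of 112 and rose in 21 (27 and 20 adjusted over the list alone, adjusted p 0.575, cyclin-A1-1, LotjaGi1g1v0264900, log2 -2.14). In the clock list 7 of 25 rose and 9 fell, also adjusted over the list alone (adjusted p 0.745, median -0.07, mean 0.01, test down). The morning gene LHY, LotjaGi3g1v0404800, went from 2.43 (SD 0.21) to 54.4 (SD 2.7, log2 4.01), and REVEILLE 6, LotjaGi5g1v0296400, from 11.1 to 1.08 (log2 -2.53). Casparian strip and suberin genes, the class MYB36 is known to control in roots, rose in 15 of 50 and fell in 18, also adjusted over the list alone (adjusted p 0.708). Dirigent protein 19, LotjaGi3g1v0200600 (128 to 1490, log2 3.63), and CASP-like 1D2, LotjaGi4g1v0346100 (16.8 to 102, log2 2.66), rose. Dirigent protein 23, LotjaGi3g1v0115400 (75.9 to 4.21, log2 -3.92), fell.

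Cytosolic ribosome genes rose in 90 of 200 and fell in 6 (85 and 5 adjusted over the list alone, median 0.41). The list's adjusted p is 0.000209, and adjusted p = 0.641 with an estimated correlation. Quantile normalization ends the call (0.596). 60S L10, LotjaGi6g1v0045500, rose from 5.34 to 163 (log2 4.83). Phloem and xylem markers fell in 27 of 49 and rose in 7, also adjusted over the list alone (adjusted p 0.0151, and adjusted p = 0.449 with an estimated correlation). Fasciclin-like protein 10, LotjaGi1g1v0464000, fell from 60.7 to 9.62 (log2 -2.57). Of the markers of other organs, 2 of 5 root and nodule genes fell and 0 rose, also adjusted over the list alone (adjusted p 0.25, glutamine synthetase nodule isozyme, LotjaGi2g1v0192900, log2 -1.33). Reproductive markers rose in 9 of 34 and fell in 17 (9 and 19 adjusted over the list alone, adjusted p 0.144). Plastid-encoded transcripts, a sign of RNA quality in polyA libraries, fell in 7 of 104 and rose in 2 (median -0.50, adjusted p 0.144). Adjusted over the list alone 0 fell and 0 rose by limma, where 11 fell and 5 rose at an unadjusted p below 0.05. LotjaGiC1v0000300 went from 52.1 (SD 47) to 8.51 (SD 7.3), a log2 change of -2.42 (adjusted p 0.00232).

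**Figure D2:**
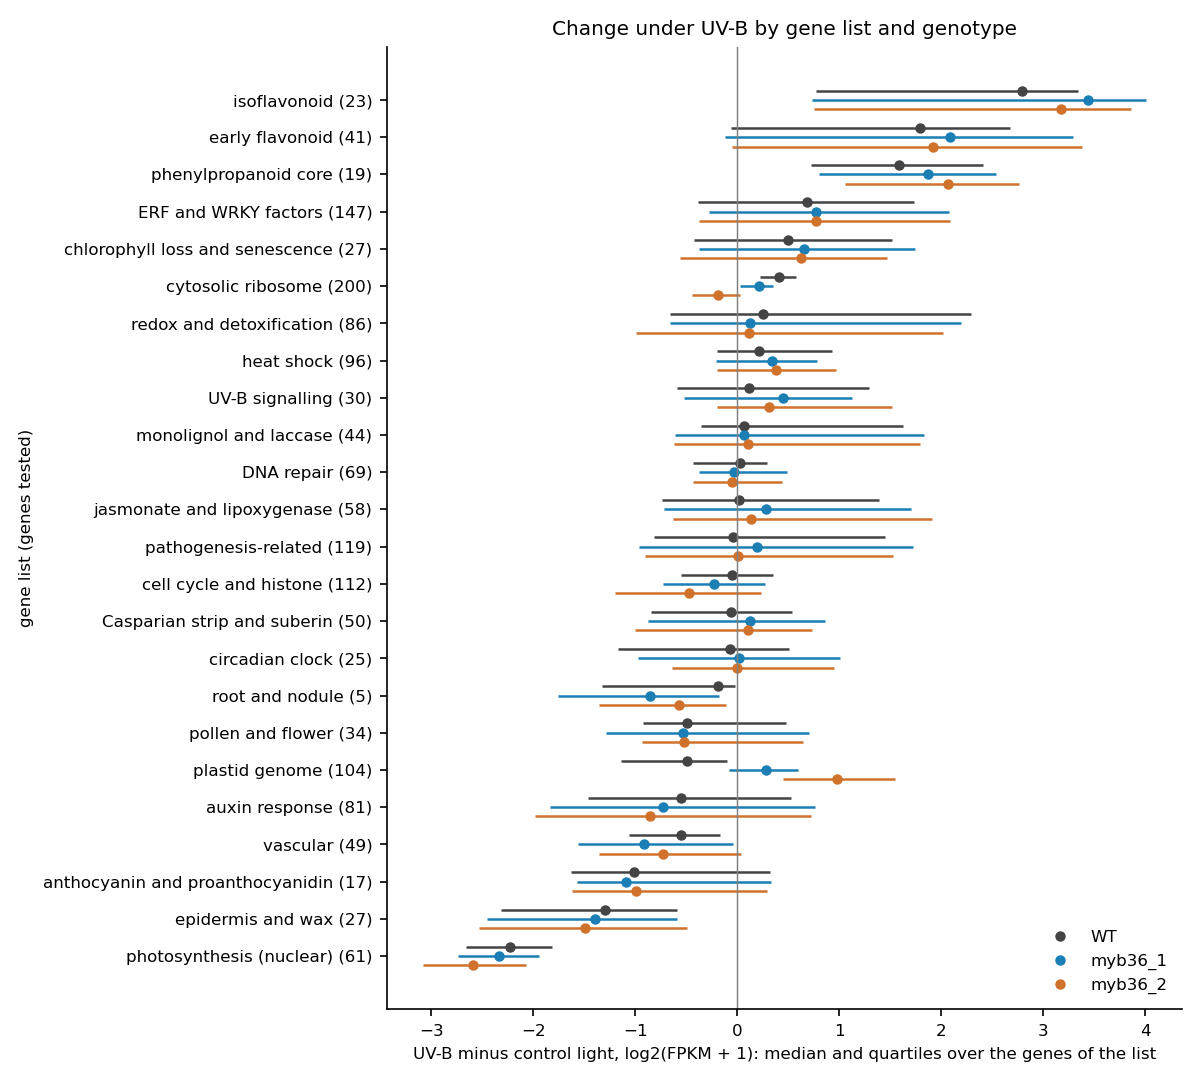
Log2 change under UV-B of the members of each gene list in WT, line 1 and line 2 (points are list medians, lines run between the quartiles of the members). Medians of the isoflavonoid list are 2.79, 3.44 and 3.17, and those of the photosynthesis list -2.23, -2.34 and -2.60.

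Both mutant lines answered UV-B much as WT did. In line 1, 6970 genes rose and 6451 fell, and in line 2, 6832 and 6519. WT and line 1 share 5758 rises and 5438 falls (2172.7 and 1900.6 expected by chance). WT and line 2 share 5651 and 5419 (2129.6 and 1920.7 expected). In lines 1 and 2, 5 and 18 genes passed in the direction opposite to WT. Across genes, which are not independent replicates, the changes in WT correlate at r = 0.958 with line 1 and 0.948 with line 2. Medians under UV-B in lines 1 and 2 were 1.87 and 2.07 for the phenylpropanoid core, 2.08 and 1.92 for early flavonoid genes, 3.44 and 3.17 for isoflavonoid genes and -2.34 and -2.60 for photosynthesis. A 2-fold threshold leaves 6094, 6909 and 6786 genes in WT, line 1 and line 2.

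In control light, early flavonoid and isoflavonoid genes leaned lower in both lines, without a gene of either list passing in both. The early flavonoid list had a median of -0.50 in line 1 (adjusted p 6.61e-05, and adjusted p = 0.704 with an estimated correlation) and -0.23 in line 2 (adjusted p 0.00681, and adjusted p = 0.489 with an estimated correlation). Of its 41 members 28 were lower in both. By limma 0 passed in both, and adjusted over the list alone 2 fell in line 1 and 0 in line 2, against 10 and 9 lower at an unadjusted p below 0.05. The isoflavonoid list had medians of -0.51 (adjusted p 0.00428, and adjusted p = 0.704 with an estimated correlation) and -0.42 (adjusted p 0.00549, and adjusted p = 0.507 with an estimated correlation). Of its 23 members 18 were lower in both. By limma 0 passed, against 6 and 4 lower at an unadjusted p below 0.05. Values for chalcone isomerase LotjaGi5g1v0359260 were 243 (SD 40) in WT, 114 (SD 14) in line 1 and 257 (SD 39) in line 2 (adjusted p 0.0572 in line 1, and 0.0356 with quantile normalization). Vestitone reductase LotjaGi1g1v0461900, of the pterocarpan branch, had 343, 211 and 258, and isoflavone 2'-hydroxylase LotjaGi4g1v0019000 had 303 (SD 200), 141 (SD 36) and 164 (SD 13). Without WT control 3 these 3 pass in line 1 (0.0217, 0.0256 and 0.000925), and the last in line 2 as well (0.00471). The phenylpropanoid core had medians of -0.25 (adjusted p 0.205) and -0.27 (adjusted p 0.00441, and adjusted p = 0.473 with an estimated correlation). Without WT control 1, the library with the highest plastid share, the calls of line 2 are lost for early flavonoid (adjusted p 0.0828), isoflavonoid (0.464) and phenylpropanoid genes (0.126), and that of line 1 for isoflavonoid genes (0.413). The medians shrink there to -0.138, -0.099 and -0.165 in line 2 and to -0.172 for isoflavonoid genes in line 1. In line 1 early flavonoid genes keep the call. Much of these differences thus rests on that library. Without WT control 2 the call of line 2 for early flavonoid genes is lost (0.103), and without line 1 control 1 or 3 that of line 1 for isoflavonoid genes (0.116 and 0.139). The medians in these fits shrink to -0.18, and to -0.295 and -0.314.

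Single genes that differed in both lines in control light include 3 whose calls no single left-out library ends. The sugar transporter SWEET10, LotjaGi1g1v0335600, was higher in both lines, with 7.54 FPKM (SD 7) in WT, 58.2 (SD 29) in line 1 and 104 (SD 33) in line 2 (log2 2.99 and 3.87, SE 0.46, adjusted p 0.00646 and 0.0007). Flavin monooxygenase 1, in Arabidopsis an enzyme of systemic acquired resistance, LotjaGi4g1v0321100, was lower, with 23.2 (SD 9.1), 4.43 (SD 2.1) and 3.67 (SD 1.3; log2 -2.15 and -2.33, adjusted p 0.000568 and 0.000254). So was the 9S-lipoxygenase LotjaGi3g1v0420500, with 385 (SD 139), 62 (SD 11) and 84.6 (SD 4.7; log2 -2.56 and -2.10, adjusted p 6.32e-05 and 0.000668). Also higher were plastidic glucose transporter 4, LotjaGi2g1v0074800 (log2 2.10 and 1.91), root phototropism protein 3, LotjaGi3g1v0013000 (1.51 and 1.23), the proline-rich protein DC2.15, LotjaGi3g1v0445300 (2.03 and 1.22), and cellulose synthase A2, LotjaGi1g1v0314700 (1.29 and 0.91). Also lower were annexin D4, LotjaGi3g1v0062600 (-1.04 and -1.09), Mediator subunit 16, LotjaGi6g1v0333900 (-0.97 and -0.88), and phosphoglycerate mutase LotjaGi1g1v0461200 (-0.97 and -0.76). These 7 lose the call in at least 1 line when 1 library is left out. Without WT control 1 adjusted p is 0.0522 for the glucose transporter, 0.143 for root phototropism protein 3, 0.0754 for DC2.15 and 0.205 for phosphoglycerate mutase in line 2. It is 0.0547 for the last in line 1, and 0.135 and 0.138 for annexin D4 in lines 1 and 2. Without WT control 2 it is 0.0594 for annexin D4 in line 1 and 0.0556 and 0.108 for Mediator 16 and phosphoglycerate mutase in line 2. Annexin D4 in line 1 reaches 0.0988 without line 1 control 1 and 0.0533 without line 1 control 3. In line 2, without control 3 it is 0.0683, 0.203, 0.254, 0.0853, 0.235, 0.0794 and 0.279 in the order given. Without control 1 it is 0.0681, 0.151, 0.0735, 0.0561 and 0.0799 for root phototropism protein 3, DC2.15, annexin D4, Mediator 16 and phosphoglycerate mutase. Without control 2 it is 0.0573 and 0.158 for root phototropism protein 3 and phosphoglycerate mutase. With only the groups compared in the fit, all 10 genes miss the threshold in line 2 (adjusted p 0.0565 to 0.103) and all but the lipoxygenase in line 1 (0.0841 to 0.383). With a pseudocount of 0.1, root phototropism protein 3 (0.0762 and 0.149), annexin D4 (0.16 and 0.135) and, in line 2, DC2.15 (0.0904) miss it. With the replicate number as a block, DC2.15 and phosphoglycerate mutase miss it in line 2 (0.0548 each).

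In all, 101 genes differed in line 1 (50 higher, 51 lower), 100 in line 2 (67 and 33) and 31 in both (21 and 10). The replicate ranges of all 31 stand apart, as do those of all 101 and all 100, so this adds nothing to the calls. Independent calls in both lines would share 0.2 and 0.1 genes, and 20 simulated data sets with the same shared WT libraries gave 0 (limma, 2678 and 2970 genes of the real data at an unadjusted p below 0.05). The former value ignores the shared WT libraries and the latter ignores shifts of whole libraries, so neither excludes chance. Across genes, the covariance of the lines' differences was 0.0373, against 0.0229 simulated, and their correlation 0.409, against 0.501 simulated. Quantile normalization gives 91 higher and 97 lower in line 1 and 55 and 50 in line 2. The counts of line 1, line 2 and both move to 52, 35 and 16 without WT control 1, 568, 560 and 240 without WT control 3, and 51 and 19 in line 1 and both without WT control 2. They move to 186 in line 1 without line 1 control 3. Line 2 has 45, 47 and 26 without line 2 control 1, 2 and 3, with 19 and 14 in both without 1 and 3. The balance of higher and lower genes moves as well: without WT control 3 it is 187 and 381 in line 1, 258 and 302 in line 2 and 67 and 173 in both, and with a pseudocount of 0.1 it is 41 and 98 in line 1. Among other lists, that of cytosolic ribosome genes was higher in line 2 (median 0.52, adjusted p 1.21e-46, and adjusted p = 0.189 with an estimated correlation). Of these 10 rose, and 156 adjusted over the list alone. The median in line 1 was -0.06 (adjusted p 0.526). The photosynthesis list was higher in line 2 (0.34, adjusted p 2.11e-09, and adjusted p = 0.41 with an estimated correlation). The jasmonate and clock lists were lower in line 2 (-0.21 and -0.15, adjusted p 0.00118 and 0.00331, and adjusted p = 0.189 for each with an estimated correlation). The plastid-encoded list was lower in both lines (-0.53 and -0.76, adjusted p 1.04e-05 and 8.8e-09, and adjusted p = 0.704 and 0.503 with an estimated correlation). Those 2 calls end without WT control 1 (0.799 and 0.139), where the median of line 1 turns to 0.03 and that of line 2 shrinks to -0.205. Casparian strip and suberin genes had medians of -0.09 in line 1 (adjusted p 0.198) and -0.001 in line 2 (adjusted p 0.812), and dirigent protein 19, LotjaGi3g1v0200600, had 128, 49.1 and 79.7 FPKM in WT, line 1 and line 2 without passing (adjusted p 0.00772 in line 1 without WT control 3).

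Under UV-B, the jasmonate list was higher in both lines than in WT, a call that neither line keeps with an estimated correlation, while no list of the flavonoid pathway passed the test. Medians of the early flavonoid list were -0.08 and -0.01 in lines 1 and 2 (adjusted p 0.335 and 0.761), of the isoflavonoid list -0.09 and -0.15 (0.722 and 0.332) and of the phenylpropanoid core 0.02 and 0.01 (0.893 and 0.761). No member of the 3 lists passed in both lines. 2-Hydroxyisoflavanone synthase LotjaGi4g1v0063000 had 2469, 2158 and 2034 FPKM in WT, line 1 and line 2, vestitone reductase LotjaGi1g1v0461900 had 2467, 2608 and 2615, and dihydroflavonol 4-reductase LotjaGi5g1v0013700 had 328, 298 and 313. In the jasmonate list 7 of 58 members rose in line 1 (median 0.29, adjusted p 7.25e-07, and adjusted p = 0.0642 with an estimated correlation). In line 2, 6 rose (median 0.17, adjusted p 0.00586, and adjusted p = 0.488 with an estimated correlation). Adjusted over the list alone 14 were higher and 1 lower in line 1, and 7 higher in line 2. In both lines 5 members passed, and by sign alone 32 were higher and 13 lower in both. Of the repressors of jasmonate signalling, TIFY 10A, LotjaGi2g1v0418800, had 47.4 FPKM (SD 3.1) in WT, 110 (SD 9.1) in line 1 and 93.5 (SD 22) in line 2 (log2 1.19 and 0.94, adjusted p 0.00108 and 0.00668). TIFY 11B, LotjaGi3g1v0411900 (55.2, 97.5 and 98.2, log2 0.79 and 0.81), and TIFY 5A, LotjaGi6g1v0310700 (4.81, 9.64 and 8.23, log2 0.87 and 0.67), were also higher in both lines. So was a model at chromosome 4, 73062894 to 73068565, annotated 9S-lipoxygenase-3, an enzyme outside jasmonate synthesis. It had 0.003 FPKM in WT, 5.37 (SD 1.3) in line 1 and 3.76 (SD 0.93) in line 2 (log2 2.65 and 2.23, adjusted p 7.74e-07 and 4.67e-06). Left-out libraries end the calls of TIFY 11B and, in line 2, TIFY 5A. Adjusted p for TIFY 11B in line 1 is 0.0768, 0.0814 and 0.0695 without WT UV-B 1, 2 and 3, and 0.116 and 0.179 without line 1 UV-B 1 and 2. In line 2 it is 0.0812, 0.0731 and 0.0663 without the WT libraries and 0.0867 and 0.133 without line 2 UV-B 1 and 2. For TIFY 5A it is 0.122 and 0.0974 without WT UV-B 1 and 2, and 0.071, 0.133 and 0.077 without line 2 UV-B 1, 2 and 3. So do only the groups compared for TIFY 10A in line 2 (0.0976), TIFY 11B (0.151 and 0.0789) and TIFY 5A (0.0731 and 0.109), and a pseudocount of 0.1 for TIFY 5A (0.399 and 0.556).

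Outside that list, a non-specific lipid-transfer protein 2, LotjaGi3g1v0152100, was higher, with 13.1 FPKM (SD 8.1) in WT, 64 (SD 17) in line 1 and 98.1 (SD 38) in line 2 (log2 2.40 and 2.97, adjusted p 0.00699 and 0.00145). Higher too were a synthase of the herbivore-induced volatile DMNT, LotjaGi3g1v0087300 (10.7, 43.1 and 43.2, log2 1.93 and 1.88), a dynein light chain, LotjaGi4g1v0455400 (24.5, 120 and 69.8, log2 2.26 and 1.44), and WRKY40, LotjaGi1g1v0378000 (4.23, 11.4 and 10.6, log2 1.23 and 1.15). The dynein gene starts at 82697700 on chromosome 4, directly after an unannotated model that ends at 82697681. That model was higher as well (log2 2.80 and 1.98), so reads shared between the models are not excluded. The metal-nicotianamine transporter YSL8, LotjaGi2g1v0208000, was lower, with 9.42 (SD 4.1), 1.22 (SD 0.69) and 0.249 (SD 0.14; log2 -2.19 and -2.98, adjusted p 0.00128 and 4.36e-05). A model annotated RAV1 at chromosome 5, 57974777 to 57983194, had 44.4 (SD 8.7), 17.4 (SD 2) and 15 (SD 0.55; log2 -1.29 and -1.49, adjusted p 0.00339 and 0.00125). Lower too were a thiamine thiazole synthase, LotjaGi3g1v0149500 (10, 3.33 and 2.38, log2 -1.38 and -1.77), and the zinc finger protein 10, LotjaGi6g1v0064000 (5.59, 1.87 and 1.72, log2 -1.27 and -1.28). Calls end for the DMNT synthase without line 1 UV-B 2 (0.0672 in line 1), WT UV-B 1 (0.0685 in line 2) or line 2 UV-B 3 (0.0776). They end for the dynein without WT UV-B 1 (0.0685 in line 2) or line 2 UV-B 2 (0.0638), and for WRKY40 without line 1 UV-B 2 (0.0529), line 2 UV-B 2 (0.0574) or line 2 UV-B 3 (0.0562). The thiazole synthase loses its call in line 1 without WT UV-B 2 (0.0742) or line 1 UV-B 2 (0.118), and zinc finger protein 10 in line 2 without line 2 UV-B 3 (0.0544). With only the groups compared in the fit, adjusted p is 0.124 and 0.0849 for the lipid-transfer protein and 0.0784 and 0.0708 for the thiazole synthase. It is 0.0769 for YSL8 and 0.18 for zinc finger protein 10 in line 1, and 0.0573 and 0.0759 for the DMNT synthase and the dynein in line 2. With a pseudocount of 0.1 it is 0.0928 for YSL8 in line 1 and 0.0574 and 0.0674 for zinc finger protein 10.

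Under UV-B 219 genes differed in line 1 (138 higher, 81 lower), 196 in line 2 (106 and 90) and 87 in both (50 and 37). Independent calls in both lines would share 0.7 and 0.3 genes, and limma found 0 shared in 20 simulated data sets. The real data have 2537 and 2544 genes per line at an unadjusted p below 0.05 by limma. The limits given for these values in control light hold here too. Across genes, the covariance of the lines' differences was 0.0626, against 0.0228 simulated, and their correlation 0.688, against 0.501 simulated. The counts of line 1, line 2 and both become 122, 82 and 41 without WT UV-B 1, 138, 106 and 54 without WT UV-B 2, and 332 in line 1 and 142 in both without WT UV-B 3. They become 145 in line 1 without line 1 UV-B 1, and 62 in line 1 and 39 in both without line 1 UV-B 2, then 122, 93 and 81 in line 2 without line 2 UV-B 1, 2 and 3, with 53 and 55 in both without 2 and 3. The balance turns without WT UV-B 3, to 138 higher and 194 lower in line 1, 100 and 177 in line 2 and 51 and 91 in both. In both it is also 19 and 22 without WT UV-B 1, and 22 and 31 without line 2 UV-B 2. The list of cell cycle and histone genes was lower in both lines, with 74 of 112 members lower and 18 higher in both and 0 past the threshold in both by limma (-0.22 and -0.15, adjusted p 6.45e-05 and 0.000188, and adjusted p = 0.489 and 0.55 with an estimated correlation). So was that of phloem and xylem markers, with 27 of 49 members lower and 7 higher in both and 2 past the threshold (-0.12 and -0.15, adjusted p 0.00634 and 0.000188, and adjusted p = 0.636 and 0.55 with an estimated correlation, 0.167 in line 1 without line 1 UV-B 2). The ribosome list was lower in line 1 (-0.24, adjusted p 2.11e-14, and adjusted p = 0.527 with an estimated correlation). The plastid-encoded list was higher in line 2 (0.70, adjusted p 8.94e-07, and adjusted p = 0.829 with an estimated correlation).

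**Figure D3:**
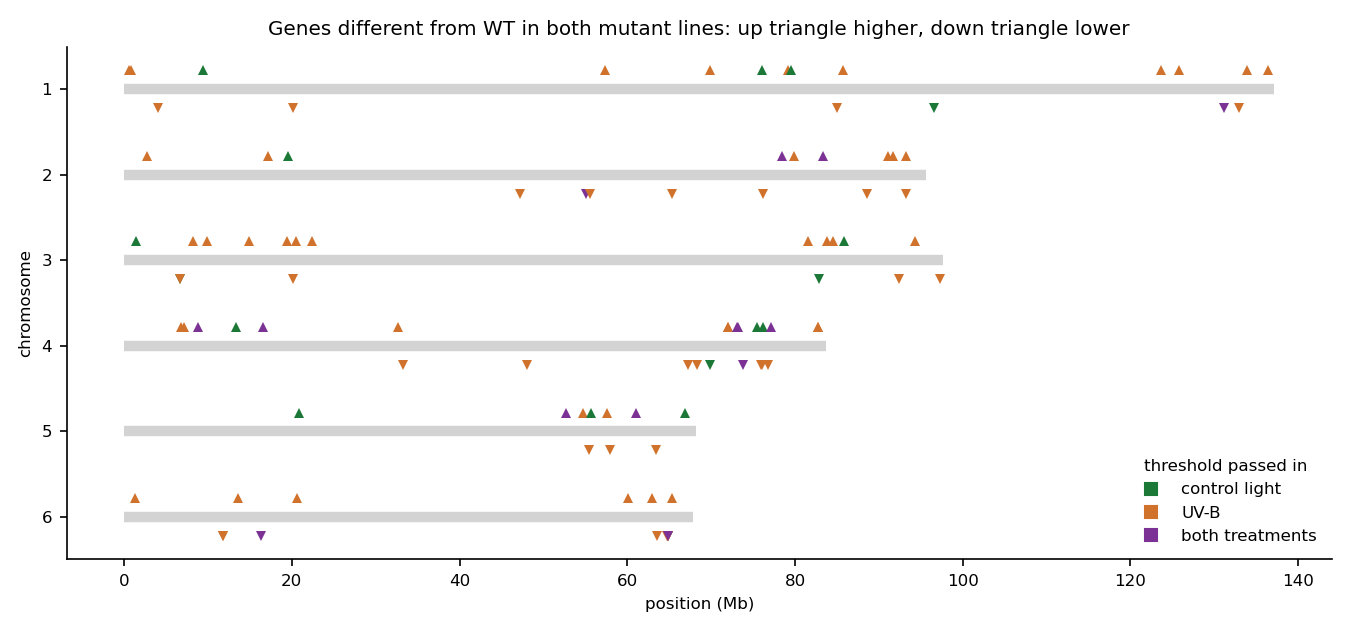
Positions, in Mb along chromosomes 1 to 6, of the 103 genes that differ from WT in both mutant lines (upward triangles higher, downward lower, colours give control light, UV-B or both). On chromosome 4, 24 of 3356 tested genes differ, and on chromosome 5, 10 of 2524.

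The test of a difference in UV-B response was passed in both lines by 3 genes. The 9S-lipoxygenase LotjaGi3g1v0420500 fell less: its changes were -5.74 in WT, -3.48 in line 1 and -3.39 in line 2, a difference of 2.25 and 2.35 (SE 0.36, adjusted p 0.0211 and 0.0215). Its level under UV-B did not pass against WT (-0.305 and 0.249, adjusted p 0.693 and 0.765). The difference thus lies in its lower control level in the lines. LotjaGi1g1v0068100, an unannotated gene (chromosome 1, 9431231 to 9434661), had 3.99 to 4.46 FPKM in WT control and 7.72 to 8.81 under UV-B. It had 6.88 to 8.67 and 5.82 to 6.67 in line 1 and 7.54 to 9.48 and 6.07 to 7.09 in line 2 (difference -1.08 and -1.14). An unannotated model at chromosome 4, 73741414 to 73745429, had 4.34 to 5.76 FPKM in WT control and 13.5 to 26.8 under UV-B and was listed at 0 in all 12 mutant libraries (difference -1.64 in each line). There the difference only mirrors the WT rise, since the transcript was not seen in the lines in either light. These last 2 genes lie outside the naming rule and were chosen after their values were seen. Left-out libraries end the call of LotjaGi3g1v0420500. In line 1 adjusted p is 0.0677 and 0.0581 without WT control 1 and 2, 0.0575 without line 1 control 2, and 0.0674 and 0.0843 without line 1 UV-B 1 and 2. In line 2 it is 0.0645 without WT control 2, 0.0863 and 0.096 without line 2 control 2 and 3, and 0.0668 and 0.065 without line 2 UV-B 1 and 3. So do only the groups compared (0.131 and 0.0769) and, in line 1, a pseudocount of 0.1 (0.0522). The left-out fits given below that leave no gene in both lines end the shared calls of the last 2 genes as well.

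The response of the jasmonate list was larger in both lines than in WT, by a median of 0.32 in line 1 (adjusted p 2.34e-08, and adjusted p = 0.0268 with an estimated correlation). In line 2 it was larger by 0.34 (adjusted p 7.45e-07, and adjusted p = 0.0757 with an estimated correlation). In line 1 a single member passed, the 9S-lipoxygenase LotjaGi3g1v0420500, an enzyme outside jasmonate synthesis whose control level was already lower in the lines. Adjusted over the list alone 12 did. In line 2 the same gene and 1 other passed, and 11 higher and 1 lower adjusted over the list alone. Other lists moved in the same comparisons, among them plastid-encoded genes (0.78 and 1.29 in lines 1 and 2), phloem and xylem markers (-0.32 and -0.28) and ribosome genes (-0.20 and -0.56), all with adjusted p = 0.27 to 0.735 with an estimated correlation. Allene oxide cyclase, an enzyme of jasmonate synthesis, LotjaGi2g1v0280800, rose more in line 2 (difference 1.41, adjusted p 0.024) and had a difference of 0.63 in line 1 (adjusted p 0.424). In line 2 the clock gene APRR5, LotjaGi1g1v0796900, rose more (1.17, adjusted p 0.0334) and YSL8, LotjaGi2g1v0208000, rose less (-2.56, adjusted p 0.024). No gene passes in line 2 without line 2 control 3 or line 2 UV-B 3, so these calls and that of allene oxide cyclase end there. In line 1 the dynein light chain LotjaGi4g1v0455400 (2.23, adjusted p 0.0239) and the auxin-conjugating GH3.1, LotjaGi2g1v0405900 (2.22, adjusted p 0.0211), rose more. A single gene passes in line 1 without WT control 1 or 2, so at most 1 of these keeps its call. For early flavonoid genes the difference was 0.42 in line 1 (adjusted p 0.0362, and adjusted p = 0.725 with an estimated correlation), and for isoflavonoid genes 0.44 (adjusted p 0.0505), where the lines' control levels had been lower. The early flavonoid call ends without WT control 1 or 2 (adjusted p 0.176 and 0.235), WT UV-B 3 (0.27), line 1 control 1 or 3 (0.415 and 0.122) or line 1 UV-B 1 or 3 (0.0966 and 0.0867).

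In all 17 genes differed in response in line 1 (13 higher, 4 lower) and 13 in line 2 (4 and 9), with 1914 and 2426 at an unadjusted p below 0.05. Without WT control 1 the counts of line 1 and both are 1 and 0. Without WT control 2 those of line 1, line 2 and both are 1, 1 and 0, and without WT control 3 they are 86, 55 and 24. Without WT UV-B 1 they are 8 and 6 in the lines, without WT UV-B 2 they are 8 and 7, and without WT UV-B 3 they are 441 in line 2 and 9 in both. In line 1 and both they are 4 and 1 without line 1 control 2, 3 and 0 without line 1 UV-B 1, 2 and 0 without line 1 UV-B 2, and 30 and 5 without line 1 UV-B 3. There are 5 in both without line 1 control 3. In line 2 and both they are 3 and 1 without line 2 control 2, 0 and 0 without line 2 control 3 (limma, 1613 and 443 at an unadjusted p below 0.05). They are 1 and 0 without line 2 UV-B 1, and 0 and 0 without line 2 UV-B 3. There are 7 in line 2 without line 2 UV-B 2. In the fits by limma that leave 0 genes in both, 394 to 643 pass in both at an unadjusted p below 0.05.

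**Figure D4:**
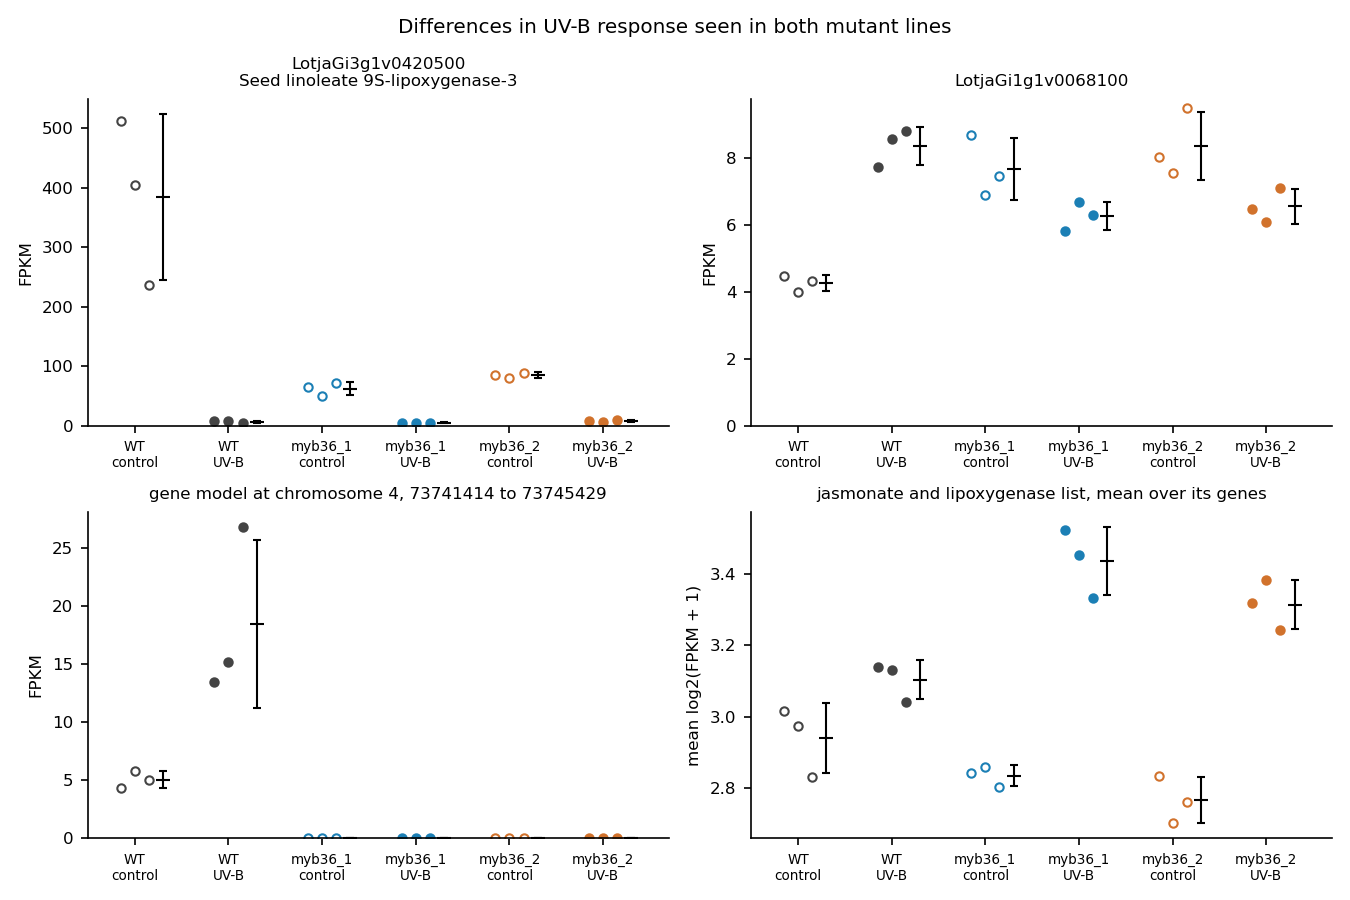
FPKM per library of the 3 genes that pass the test of a difference in UV-B response in both lines, and the mean log2(FPKM + 1) of the jasmonate list per library (points are libraries, n = 3 per group). The list mean under UV-B runs from 3.04 to 3.139 in WT, 3.332 to 3.523 in line 1 and 3.242 to 3.381 in line 2.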

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

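These are results where the UV-B response of a mutant line differed from that of WT by a test of that difference. The tests of random placement and of reads per molecule, and the splits of the jasmonate list, were chosen only after the result was seen; the other predictions were written before their tests ran.

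Single genes with a different response number 17 in line 1 and 13 in line 2, and 3 differ in both lines: LotjaGi3g1v0420500 (2.255 and 2.35), LotjaGi1g1v0068100 (-1.084 and -1.138) and the model at chromosome 4, 73741414 to 73745429 (-1.636 in each). Chance is not excluded for the counts per line: of 100 splits of the libraries, 12 gave at least 17 genes (highest other 875) and 5 gave at least 13 (highest other 135), and counts that far above the real ones point to a structure among the libraries. The count of 3 shared genes was reached by 1 of 100 splits, the real one (highest other 1), but this does not exclude chance. The model at chromosome 4 is listed at 0 in every mutant library, which favours the real split in advance. Leaving out 1 of several libraries also leaves no shared gene, as given above.

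Lists with a different response, as medians of the members' differences, are in line 1: early flavonoid genes 0.416, photosynthesis -0.126, chlorophyll loss 0.187, jasmonate 0.324, cell cycle -0.159, ribosome -0.2, phloem and xylem -0.318 and plastid-encoded genes 0.78. In line 2 they are the phenylpropanoid core 0.279, UV-B signalling 0.108, photosynthesis -0.381, jasmonate 0.336, ERF and WRKY factors 0.102, cell cycle -0.202, clock 0.159, ribosome -0.562, phloem and xylem -0.278 and plastid-encoded genes 1.291. With an estimated correlation adjusted p is 0.0268 for the jasmonate list in line 1 and 0.0757 in line 2, and for the rest 0.725 to 0.735 in line 1 and 0.27 to 0.659 in line 2. Of these lists, 8 in line 2 and 2 in line 1 also differ from WT in control light, in the opposite direction. In line 2 these are the ribosome 0.52, photosynthesis 0.34, cell cycle 0.12, jasmonate -0.21, the phenylpropanoid core -0.27, the clock -0.15, ERF and WRKY factors -0.11 and plastid-encoded genes -0.76 (adjusted p 1.21e-46 to 0.0315), and in line 1 early flavonoid genes -0.50 and plastid-encoded genes -0.53 (6.61e-05 and 1.04e-05). None of these control-light calls holds with an estimated correlation. Without WT control 1 those of the phenylpropanoid core, ERF and WRKY factors, the cell cycle and, in both lines, plastid-encoded genes end. With reads per molecule as a covariate the clock medians of line 2 are 0.078 in the response and -0.077 in control light.

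Left-out libraries end several of these list calls. In the fits that end a call the medians in line 1 are 0.279 to 0.445 for early flavonoid genes, -0.097 to -0.055 for photosynthesis, 0.121 to 0.223 for chlorophyll loss, -0.102 to -0.05 for the cell cycle, and 0.179 and 0.437 for plastid-encoded genes. In line 2 they are 0.177 to 0.243 for the phenylpropanoid core, 0.078 to 0.137 for UV-B signalling, 0.02 to 0.107 for ERF and WRKY factors, 0.125 for the clock, and -0.178 and -0.159 for phloem and xylem. The adjusted p is given next. In line 1 early flavonoid genes lose it without WT control 1 or 2 (0.176 and 0.235), WT UV-B 3 (0.27), line 1 control 1 or 3 (0.415 and 0.122) or line 1 UV-B 1 or 3 (0.0966 and 0.0867), and photosynthesis without WT control 1 (0.176), WT UV-B 2 (0.12), line 1 control 3 (0.0658) or line 1 UV-B 2 (0.107). Chlorophyll loss does so without WT control 1 or 3 (0.0665 and 0.0747), WT UV-B 3 (0.176), line 1 control 1 (0.415) or line 1 UV-B 2 or 3 (0.0707 and 0.0572). Cell cycle genes do so without WT control 1 (0.176), WT UV-B 1 (0.148), line 1 control 1 (0.529) or line 1 UV-B 2 (0.0613), and plastid-encoded genes without WT control 1 (0.66) or line 1 UV-B 3 (0.0658). In line 2 the phenylpropanoid core loses it without WT control 1 (0.14), WT UV-B 3 (0.0615) or line 2 UV-B 1 (0.0583), the clock without WT control 3 (0.0807), and phloem and xylem without WT control 2 (0.0738) or line 2 UV-B 3 (0.149). ERF and WRKY factors do so without WT control 1 or 2 (0.279 and 0.0522), WT UV-B 3 (0.0741), line 2 control 2 (0.0854) or line 2 UV-B 1 or 2 (0.085 and 0.119). UV-B signalling does so without WT control 2 or 3 (0.0519 and 0.16), WT UV-B 3 (0.233), line 2 control 1, 2 or 3 (0.0509, 0.0532 and 0.0618) or line 2 UV-B 1 or 3 (0.085 and 0.0708).

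The jasmonate list had a larger UV-B response in both lines. The number of reads per molecule is argued against as the source: with it as a covariate the medians are 0.344 and 0.331. A single WT library is argued against as well, since the lowest median without any 1 of the 6 is 0.244. All 6 mutant UV-B libraries lie above the 3 WT UV-B libraries, which had been written down beforehand as evidence against an effect of the shared WT libraries; that criterion was wrong, because 9 of the 84 ways of taking 3 of the 9 UV-B libraries as WT put at least 1 of the 24 lists as far apart (share 0.107). A jasmonate response that is truly stronger in the mutants and a chance property of the WT samples both stay open.

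Genes that differ in both lines lie close together: 37 of 103 have another within 500 kb. Random placement is argued against (median 23 in 10000 matched random lists, permutation p 0.0085), and so are neighbouring models that share reads, with 33 genes left when partners within 10 kb are ignored (permutation p 0.0417); for control light alone the count is 4 of 31 (permutation p 0.305), and for UV-B alone 30 of 87 (permutation p 0.0059). A run at chromosome 6, 64765370 to 64875503, holds 6 such genes of 15 tested, with Mediator 16 at -0.97 and -0.88 in control light and -0.95 and -1.11 under UV-B. Of the 15, 13 are lower in all 4 comparisons of a line with WT and 0 are higher in all 4, which goes with the blocks described next, though the run was picked because its genes differ. Blocks of sequence that differ between WT and both lines would lower or raise genes in either light; 19 of 30 clustered genes and 33 of 57 others have the same sign in control light (one-sided Fisher's exact p 0.399). A p at or above 0.05 had been set as counting against such blocks, but this was changed after the result to leave them open, since a p that misses the threshold with 30 and 57 genes does not show equal shares. On chromosome 4, a model at 73741414 to 73745429 is listed at 0 in every mutant library and at 4.34 to 26.8 FPKM in WT. Models that start at 73062894 and 73148868 are higher in all 4 comparisons (1.93 to 2.65). Of the 9 genes tested from 73062894 to 73153678, 2 are higher in all 4 and 2 lower. These models go with such blocks, but they too were picked because they differ.

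Genes that differ in both lines could reflect how the libraries were made, as 4 of the 6 libraries above 20 reads per molecule are from line 1. With the covariate, 83 of the 87 UV-B genes kept their call, which argues there against an effect linear in log2 reads per molecule. In control light 19 of 31 did, which leaves such an effect open. Other effects of how the libraries were made were not tested with the covariate. Under UV-B 1 of 84 splits reached 87, the real one (highest other 5), which argues there against chance among interchangeable libraries. In the other splits the libraries not taken as WT are shared between the lines at random, which mixes genotypes. A shift common to the libraries of a group thus favours the real split in advance and is not excluded. In control light 2 of 84 reached 31, a share below 0.05. The split other than the real one gave 37, more than the real count, with WT control 1 and 2 and line 1 control 2 in 1 group. Chance is therefore not excluded in control light. Each comparison of 3 with 3 libraries has 10 splits, too few for a share below 0.05: highest others are 1, 1 and 0 against 12772, 13421 and 13351 genes for UV-B in WT, line 1 and line 2; 318 against 101 and 2 against 100 for lines 1 and 2 in control light; and 376 against 219 and 2 against 196 under UV-B. Splits that reached the real count numbered 2 for line 1 in each light and 1 in the others; the 376 came from WT UV-B 1 and 2 with line 1 UV-B 1, the libraries with the fewest reads per molecule of those 6, and both 318 and 376 point to a structure of the samples.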

How the results depend on the processing

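Array weights, the covariate, the fit without 6 libraries, voom and the left-out libraries for the gene lists are tests chosen only after the result was seen. The UV-B counts stayed within 1.5 times those reported under every alternative except a 2-fold threshold, at 9804 to 15926 in WT, 10058 to 14291 in line 1 and 10119 to 16407 in line 2. Without any 1 library they are 11561 to 12424 genes in WT, 12650 to 13052 in line 1 and 12031 to 12528 in line 2. The counts of differences between genotypes moved many-fold with the weight given to single libraries. In simulated data without shifts of whole libraries, 2-fold changes were found in 76.1% of genes of at least 5 FPKM and 1.5-fold changes in 23.9% (line 1 in control light). When libraries were left out 1 gene list call turned, that of plastid-encoded transcripts of line 1 in control light (median -0.526, and 0.03 without WT control 1, adjusted p 0.799). The balance of higher and lower genes turned more often: genes shared by both lines go from 21 higher and 10 lower to 67 and 173 without WT control 3, and from 50 and 37 to 51 and 91 without WT UV-B 3. With quantile normalization the UV-B counts have more falls than rises (6080 rises and 6238 falls in WT). The cause of each shift below was not tested, except where fewer samples or a stricter threshold is the alternative itself.

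With a 2-fold threshold UV-B counts are 6094, 6909 and 6786 in WT, line 1 and line 2; the lines against WT 55, 47 and, in both, 20 in control light, and 104, 93 and 45 under UV-B. With no filter line 1 in control light has 176 genes and its response difference 9. With quantile normalization these are 188 and 10. With only the groups compared control light gives 7, 13 and 16 in line 1, line 2 and both, UV-B 48, 40 and 50, and the response of line 1 gives 1. There each line's count comes from a fit of that line and WT, and the count in both from a fit of both lines with WT, so it can exceed either line's. With a pseudocount of 0.1 line 2 in control light has 64, the shared response differences are 1, and 0 MYB36 differences remain (limma; unadjusted p 0.0142 and 0.00112 for the 2 found before). With an estimated correlation 2 of 70 gene list calls hold, against 68 to 71 with the replicate block, a pseudocount of 0.1, quantile normalization or the reads-per-molecule covariate. Without 1 library at a time fewer remain of the calls that library enters, from 25 of 42 without WT control 1 and 20 of 26 without line 2 UV-B 3 to 18 of 18 without line 1 control 2.

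With array weights (0.212 for WT UV-B 3 to 4.311 for WT control 2) control light gives 862, 5822 and 529 in line 1, line 2 and both, UV-B 990, 3277 and 733, and the responses 110, 4623 and 95. With the reads-per-molecule covariate control light gives 64 and 47. Without the 6 libraries above 20 reads per molecule, which leaves 1 library in each line 1 group that is assumed to vary like the other groups, control light gives 15, 370 and 10, UV-B 48, 1138 and 36, and the responses 0, 897 and 0 (limma; 1608 in line 1 and 641 in both at an unadjusted p below 0.05). With voom line 2 in control light has 202, UV-B gives 117, 87 and 42, and the responses 1, 4 and 0 (limma; 556 in both at an unadjusted p below 0.05). Of the 31 genes shared in control light and the 87 under UV-B, 31 and 87 remained with array weights, 19 and 83 with the covariate, 7 and 23 without the 6 libraries, 20 and 38 with voom, 30 and 78 with quantile normalization, 24 and 57 with the other pseudocount, and 23 and 59 with the stricter filter.

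Without 1 library at a time, control light gives 51 to 568 genes in line 1, 26 to 560 in line 2 and 14 to 240 in both, UV-B 62 to 332, 81 to 277 and 39 to 142, and the responses 1 to 86, 0 to 441 and 0 to 24; the MYB36 differences are 1 to 3 (1 without WT UV-B 2 or 3 or any line 1 UV-B library, 3 without WT control 1). The highest counts come without WT control 3 (568, 560, 240, 86 and 24, with 31 of the 31 shared genes kept) and WT UV-B 3 (332, 277, 142 and 441, with 69 of the 87 kept). Of 157 tests of named genes past the threshold, 140 remained with a pseudocount of 0.1 and 154 with quantile normalization. With only the groups compared 116 remained, and 126 did in every fit without 1 library. In these fits 0 turned sign. Most of the 157 are tests of the UV-B change in WT. The 41 calls lost with only the groups compared and the 31 lost without 1 library are mostly differences between genotypes. The pooled counts thus overstate how stable the genotype calls are. With the replicate number as a block (each library correlates best with its own number in 0 to 3 of 3 cases per pair of groups), control light gives 108, 78 (69 of the 100 kept) and 29, UV-B 215, 201 and 87, the responses 19, 14 and 4, and 152 of the 157 named tests remain.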

Other observations

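The comparison of the lists by left-out libraries and the choice of the genes named here are tests and choices made only after the result was seen. Among genes that differ from WT in both lines and have not been named above, several differ in both lights. Thioredoxin H2, LotjaGi2g1v0309700, had log2 0.92 and 0.92 in lines 1 and 2 in control light and 0.84 and 1.28 under UV-B. It lies close to the threshold (limma adjusted p 0.0379 and 0.0419, then 0.0419 and 0.00239). The others are a FAR1-related protein, LotjaGi4g1v0393400 (1.90 and 1.68, then 1.58 and 1.37, adjusted p 0.000194 to 0.00276), and a GPI-anchored protein, LotjaGi5g1v0220200 (2.29 and 2.30, then 2.36 and 2.50, adjusted p 1.3e-05 to 6.32e-05). Within a line, 12 higher and 13 lower genes of line 1 and 12 and 12 of line 2 passed in both lights with the same sign, and 1 gene of line 1 passed with opposite signs. The model at chromosome 4, 73062894 to 73068565, annotated as a 9S-lipoxygenase, had 0 FPKM listed in WT control and 4.44 (SD 1.3) and 2.96 (SD 0.28) in lines 1 and 2.

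Under UV-B alone, allene oxide cyclase LotjaGi1g1v0690000, which acts in jasmonate synthesis, was higher in both lines (1.97 and 1.41; adjusted p 0.00141 and 0.0184). SAG12, LotjaGi6g1v0324100, a cysteine protease gene used as a senescence marker, had 336 (SD 93) FPKM in WT, 767 (SD 36) in line 1 and 736 (SD 130) in line 2 under UV-B, and did not pass. Fasciclin-like protein 11, LotjaGi4g1v0380700, a gene of secondary walls, was lower in both lines (5.72, 2.03 and 1.18, log2 -1.13 and -1.61). In line 1 the call is lost without WT UV-B 2 (adjusted p 0.129), WT UV-B 3 (0.0597), line 1 UV-B 1 (0.0614), line 1 UV-B 2 (0.14) or line 1 UV-B 3 (0.0626). It is also lost there with quantile normalization and with only the groups compared.

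Further list calls have small medians and end when 1 library is left out, given here with the adjusted p without it. In line 2 in control light these are lignin -0.09 (adjusted p 0.0387; 0.11, 0.0513 and 0.0519 without WT control 1, 2 and 3, and 0.0515 and 0.0725 without line 2 control 2 and 3) and redox 0.12 (0.0315; 0.41 without WT control 3, and 0.13 and 0.054 without line 2 control 1 and 3). They include ERF and WRKY factors at -0.11 (0.00926, then 0.247 without WT control 1 and 0.0647 without line 2 control 2) and the cell cycle at 0.12 (0.0315, then 0.501 and 0.0519 without WT control 1 and 3 and 0.185 without line 2 control 2). Wax markers stand at -0.09 (0.0315, then 0.107 and 0.0702 without WT control 1 and 2, and 0.106 and 0.0561 without line 2 control 1 and 3). With an estimated correlation adjusted p = 0.287 to 0.541 for these 5. In the fits that end these calls the medians are -0.118 to -0.062 for lignin and 0.068 to 0.092 for redox. They are -0.073 and -0.043 for ERF and WRKY factors, 0.084 to 0.149 for the cell cycle and -0.143 to -0.052 for wax. With reads per molecule as a covariate the medians of the 5 are, in the order given, -0.106, 0.014, -0.126, 0.091 and -0.188. Under UV-B they are heat shock 0.08 in line 2 (0.0355, then 0.08 and 0.266 without WT UV-B 1 and 3 and 0.624 without line 2 UV-B 3, and adjusted p = 0.764 with an estimated correlation), wax -0.16 in line 2 (0.0127, then 0.0526 without WT UV-B 1, and adjusted p = 0.469 with an estimated correlation) and photosynthesis -0.14 in line 1 (0.00175, then 0.133 without WT UV-B 2 and 0.244 without line 1 UV-B 2, and adjusted p = 0.87 with an estimated correlation). In these left-out fits the medians are 0.039 to 0.095 for heat shock, -0.076 for wax, and -0.085 and -0.03 for photosynthesis.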
